A study of Nicotiana benthamiana and Arabidopsis thaliana with 21 samples.

How the data were processed

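RNA-seq was done on ribosome-depleted leaf RNA of Arabidopsis thaliana and Nicotiana benthamiana, with 3 libraries in each of 7 groups, 21 libraries in all. The Arabidopsis groups were wild type (Col-0), pel1 (SAIL_881_B10) and hbs1 (WiscDsLox477-480D24), grown at 21 °C with 16 h light and 8 h dark. The N. benthamiana groups were plants in which Pelota or, as the control, PDS was silenced with a Tobacco rattle virus vector. There were experiment 1 (replicates 1 to 3) and experiment 2 (replicates 4 to 6), at 23 °C with 14 h light and 10 h dark. Per the labels, experiment 1 used the TruSeq v2 kit and experiment 2 the ScriptSeq v2 kit, so the kit and the experiment cannot be separated. Per the file headers, Pelota replicates 2 and 3 of experiment 1 were read from a folder whose name ends in II, and they were kept in experiment 1 as labelled. The median log2 5'/3' coverage of their multi-exon genes (0.127 and 0.106) lay near that of the other libraries of experiment 1 (0.0686 to 0.114) and apart from experiment 2 (0.580 to 0.746).

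Per the labels, the authors aligned the Arabidopsis reads and those of experiment 1 with HISAT2 2.1.0, assembled transcripts with StringTie 1.3.3b and compared groups with DESeq2 1.18.1. Per the labels, experiment 2 was processed with TopHat2 2.1.1, Cufflinks 2.2.1 and StringTie 1.3.3b. The file headers of those libraries point to an alignment folder named for Hisat2. Which aligner gave the deposited values is not given in the sources used here. The deposited library files are StringTie assemblies guided by the TAIR10 or Niben101 gene models, as the file headers state, and give for each transcript coverage (mean reads per base), FPKM and TPM, and for each exon coverage. Assembly was not limited to the guide, so transcripts outside it are included and transcripts that were not assembled are not listed, which was counted here as 0. The authors also deposited a result table per comparison, with a mean normalized signal, a log2 fold change, a p-value and an adjusted p-value per gene or merged locus, whose column names are those of DESeq2 per the file headers. Most lines of the authors' tables are merged loci with no gene name, and these were used for counts alone. A deposited workbook of the authors gives, for each miRNA target, a ratio of the 5'/3' coverage ratio in mutant or silenced plants to that in controls, with a p-value for N. benthamiana per the file headers. How coverage was counted, which replicates entered and which test was used are not given in the sources used here.

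Gene TPM was the sum over the transcripts of a reference gene. A transcript outside the reference was added to the gene with the largest exon overlap on its strand, or on either strand where it had none. That overlap had to be at least 50% of the exon length of the transcript or of the gene. Groups were compared with limma 3.58.1 (R 4.3.3, statmod 1.5.0; trend and robust settings) on log2 of TPM plus 1, for genes with TPM of at least 1 in at least 3 libraries. The 9 Arabidopsis libraries formed a single fit and the N. benthamiana experiments were fitted apart, except in the test of the difference between them. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons, tests, lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Raw counts were not used, so no count model was run. Folds are log2, and no fold is given for a gene listed at 0 in all libraries of a group.

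Gene lists (328 entries kept, 3 dropped whose locus or symbol the reference annotation does not give, 21 lists) were tested with camera at a preset correlation of 0.01 and at an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The lists were miRNA targets, nonstop decay and exosome, 5' decay and nonsense-mediated decay, RNA silencing machinery, tasiRNA loci and targets, salicylate and immune response, jasmonate response, cold and dehydration, heat and protein folding, and the clock. The others were senescence, flowering markers, photosynthesis, iron, phosphate, anthocyanin synthesis, root markers, seed markers, cytosolic ribosomal proteins, and chloroplast- and mitochondrion-encoded genes. The genes of the authors' deposited table of N. benthamiana miRNA targets were added as a list after the data were seen. The genes named are the targeted genes and, per comparison, the 8 largest increases and 8 largest decreases that passed, had a symbol, a mean TPM of at least 1 in a group and no overlap between groups. Named too are up to 4 members per list by smallest p, and miRNA targets that passed or, where none did, the 5 with the smallest p. In N. benthamiana, where genes have no symbols, up to 2 identifiers each way are given. Genes outside that rule are the members of the sulfur list, the genes that passed in opposite directions in the mutants and the genes next to PEL1, and they were chosen after their values were seen.

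The authors' ratio table has no values per library, so the planned test per library was run on exon coverage of the Arabidopsis library files, an alternative chosen after the data were seen. Cleavage sites were searched by complementarity between 75 listed targets and their miRNAs (mismatch score of at most 4, positions 2 to 13 counted double, cleavage between positions 10 and 11). A site was kept for 29 targets, 24 of them in the coding region, and 9 had exons on both sides with coverage above 0 in every library. The 5'/3' ratio of a target was the mean coverage per base, summed over its transcripts, of the exons upstream of the exon with the site over that of the exons downstream. The mean of its log2 over targets was compared between groups with an exact two-sided permutation test of libraries, and single targets with limma without the trend setting. In N. benthamiana no genome sequence was at hand and the ratio per library is not analysed here. Background was the ratio of the 5' to the 3' part of the exons of 7589 other genes with at least 4 exons, and 10000 random sets of genes matched on coverage, 60 per target, were given random sites. Permutation tests across targets used 100000 draws, and those across families 10000. Coordinates are TAIR10, and of 19280 loci compared between the files and the reference annotation 19275 (99.97%) overlapped.

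Depth in aligned bases, estimated as the median of coverage over FPKM among transcripts with FPKM above 1, was 5195.3 to 6167.9 Mb in Arabidopsis, 3934.7 to 5571.8 in experiment 1 and 554.7 to 2131 in experiment 2. Library correlations across genes were 0.909 to 0.948 within Arabidopsis groups and 0.678 to 0.839 within those of experiment 2. Chloroplast and mitochondrial transcripts made up 33.4% to 61.0% of TPM in Arabidopsis, psbA alone 5.65% to 41.1%. The psbA share varied within groups, at 34.3%, 35.0% and 5.65% in wild type 1 to 3, 13.3%, 41.1% and 31.7% in hbs1 and 24.0%, 23.9% and 22.1% in pel1. Transcripts outside the reference that were added to genes made up 19.8% of TPM in hbs1 1 and 1.3% to 10.0% in the other Arabidopsis libraries. On simulated data with 100 genes changed by log2 1 and 100 by log2 2, limma recovered 22% and 82% for pel1 (2 false calls), 17% and 75% for hbs1 (8) and 20% and 78% for pel1 against hbs1 (2). It recovered 29% and 90% for experiment 1 (4) and 0% and 0% for experiment 2 (0), where a low count says little about what changed. The site search found 200 of 200 planted sites. The test of single targets recovered 98.3% of changes of log2 2 at an SD of 0.5, with 15 false calls.

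Alternatives were a pseudocount of 0.1, no filter or TPM of at least 5, FPKM, median-centred or quantile-normalized values, the replicate number as a block, the spread of the 6 libraries compared, the authors' table, and leaving out each library in turn. For the 5'/3' ratio they were the median over targets, targets above the median coverage, a pseudocount of 10 and values relative to the library median over targets. Added after the data were seen were transcripts matching the reference alone, genes above 0 in every library, TPM rescaled over nuclear genes, median-centred values for the lists, a site score of at most 3, and subtraction of the background ratio. The pel1 and hbs1 folds share controls, which was simulated with 100 draws. The Pelota and PDS genes of N. benthamiana, and transcripts outside reference genes were left out, since identifiers without a name or assembled anew in each library cannot be compared. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.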

Results

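PEL1, the Arabidopsis Pelota protein that recognizes ribosomes stalled at the end of a message, was listed at 0 TPM in all 3 pel1 libraries. It stood at 9.13, 10.4 and 13.1 TPM in the wild-type libraries and at 8.81, 9.57 and 8.29 TPM in the hbs1 libraries (chromosome 4, 13803268 to 13808031, TAIR10). HBS1, the GTPase partner of Pelota, stood at 2.83, 1.55 and 2.75 TPM in hbs1, 4.61, 3.87 and 6.86 TPM in the wild type and 4.59, 5.66 and 6.82 TPM in pel1 (chromosome 5, 3359832 to 3364623). None of the hbs1 signal came from a transcript that matched a reference HBS1 model (0 TPM in all 3 hbs1 libraries), whereas such transcripts stood at 4.61, 3.03 and 6.86 TPM in the wild type. For all HBS1 transcripts the difference from the wild type did not pass (log2 fold change -0.85, SE 0.26, adjusted p = 0.0858, limma with Benjamini-Hochberg adjustment, 3 libraries per group). HBS1 was higher in pel1 than in hbs1 (log2 1.00, SE 0.26, adjusted p = 0.0432). The replicates are samples as the labels number them. The p-values of limma and of the permutation tests of libraries measure the spread between these samples alone. Permutation p-values across targets or families measure the spread across targets, not between samples, and camera p-values rank a list against other genes. The Pelota and PDS genes of N. benthamiana are not analysed here.

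The mean ratio of coverage upstream to coverage downstream of the cleavage site, over 9 miRNA targets, was higher in the libraries of both Arabidopsis mutants than in those of the wild type. Over these targets (ARF10, ARF16, ARF17, MYB33, MYB65, PHV, CNA, AGO1 and TOE2), the mean log2 5'/3' coverage ratio per library was 0.06 ± 0.02 in the wild type, 0.76 ± 0.14 in pel1 and 0.97 ± 0.37 in hbs1 (mean ± SD, n = 3 libraries per group). The differences from the wild type were 0.70 for pel1 and 0.91 for hbs1, each with p = 0.1 in an exact two-sided permutation test, the smallest p that 3 against 3 libraries can give. The 3 mutant libraries of each line lay above the 3 wild-type libraries (pel1 0.65, 0.72 and 0.92, hbs1 1.40, 0.73 and 0.78, wild type 0.06, 0.08 and 0.05). The ratio was higher for 8 of 9 targets in pel1 and 9 of 9 in hbs1, with a median difference over targets of 0.53 and 0.83. In pel1 the mean rested most on ARF17 (2.91) and MYB33 (1.37), while PHV (0.04), TOE2 (0.06), ARF16 (0.16) and AGO1 (-0.31) differed little. In hbs1 the mean rested most on ARF17 (2.52) and MYB33 (1.60). TOE2, whose 0.83 is the hbs1 median, rested on hbs1 replicate 1 (log2 ratio 3.76, with a 3' coverage of 0.39). Its other hbs1 libraries gave 1.25 and 0.21, and the wild type 0.78 to 1.00. The count of 9 of 9 therefore depends on that library. The median of 7589 other multi-exon genes moved by 0.03 in either mutant (exact p = 0.1). Between the mutants the ratio did not differ detectably (log2 -0.21, exact two-sided permutation p = 0.5). Among 10000 random sets of 9 genes matched to the targets on coverage, 2 changed as much as the targets in pel1 and 0 in hbs1, and the largest random changes were 0.74 and 0.64.

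**Figure D1:**
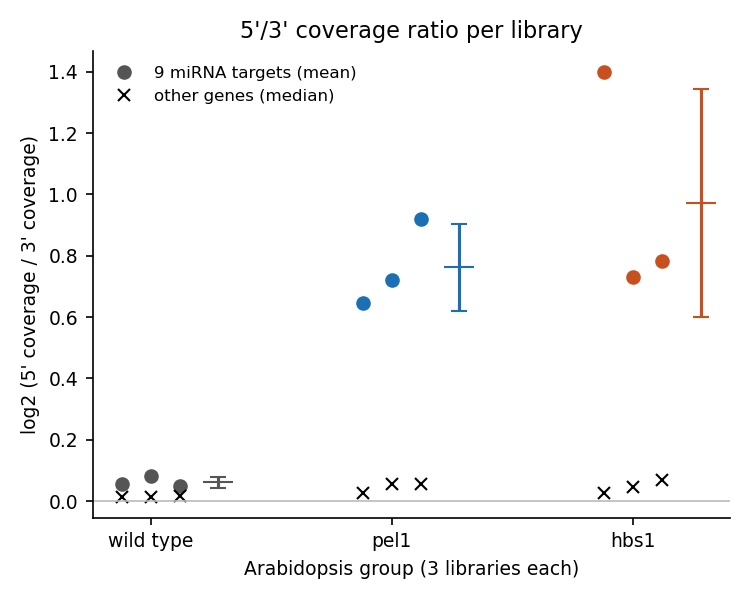
Mean log2 ratio of 5' to 3' coverage over 9 miRNA targets (filled points, 1 per library) and median over 7589 other multi-exon genes (crosses) in wild type, pel1 and hbs1, with the mean and SD of the 3 libraries beside each group. The wild-type libraries sit between 0.05 and 0.08, and the mutant libraries between 0.65 and 1.40.

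Coverage on the 5' side of the site was higher in both mutants. On the 3' side it moved little in pel1, and in hbs1 it was lower by about as much as the 5' side was higher. With 3 libraries per group no exact p can go under 0.1, so these p-values cannot separate the sides. The 9 targets' own coverage differed by log2 0.71 on the 5' side and 0.01 on the 3' side in pel1 (exact two-sided permutation p = 0.1 and 1), and by 0.44 and -0.47 in hbs1 (exact p = 0.1 and 0.2). Relative to the same side of 540 control genes, 5' coverage of the 9 targets was higher by log2 0.64 in pel1 and 0.56 in hbs1 (exact two-sided permutation p = 0.1 each, n = 3 per group). Their 3' coverage differed by -0.03 (exact p = 0.8) and -0.32 (exact p = 0.5). ARF17, an auxin response factor cleaved through miR160, had the largest single change. Its 5'/3' ratio rose by log2 2.91 in pel1 (SE 0.44, adjusted p = 0.000186, limma with Benjamini-Hochberg adjustment over the 9 targets) and 2.52 in hbs1 (SE 0.44, adjusted p = 0.000733). Coverage of ARF17 upstream of the site, per Gb of aligned bases, was 2.94, 3.51 and 3.57 in the wild type, 16.5, 20.7 and 16.9 in pel1 and 12.8, 13.5 and 15.6 in hbs1. Downstream it was 5.77, 4.03 and 4.93 in the wild type, 6.31, 2.92 and 2.29 in pel1 and 2.93, 5.09 and 2.97 in hbs1. The mapped site lay in exon 2 of 3 (chromosome 1, 29274189 to 29274209). MYB33, a regulator of programmed cell death in the anther tapetum and a miR159 target, followed with 1.37 in pel1 (SE 0.32, adjusted p = 0.00413) and 1.60 in hbs1 (SE 0.32, adjusted p = 0.00119). Its site lay in exon 4 of 5 (chromosome 5, 1839579 to 1839599). ARF10 (miR160, log2 1.02, SE 0.39) and CNA (miR166, log2 0.86, SE 0.33) passed in hbs1 with adjusted p = 0.0486 each, and the other 5 targets passed in neither mutant. The calls for ARF10 and CNA ended when any of the 3 wild-type libraries was left out, whereas those for ARF17 and MYB33 did not. Relative to the library median over targets, MYB33 lost its call in pel1 (0.65, adjusted p = 0.296, limma) and hbs1 (0.63, adjusted p = 0.264), and ARF17 kept it (2.19 and 1.55). No target differed between pel1 and hbs1 (limma, smallest unadjusted p = 0.122, 0 of 9 at an unadjusted p under 0.05).

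**Figure D2:**
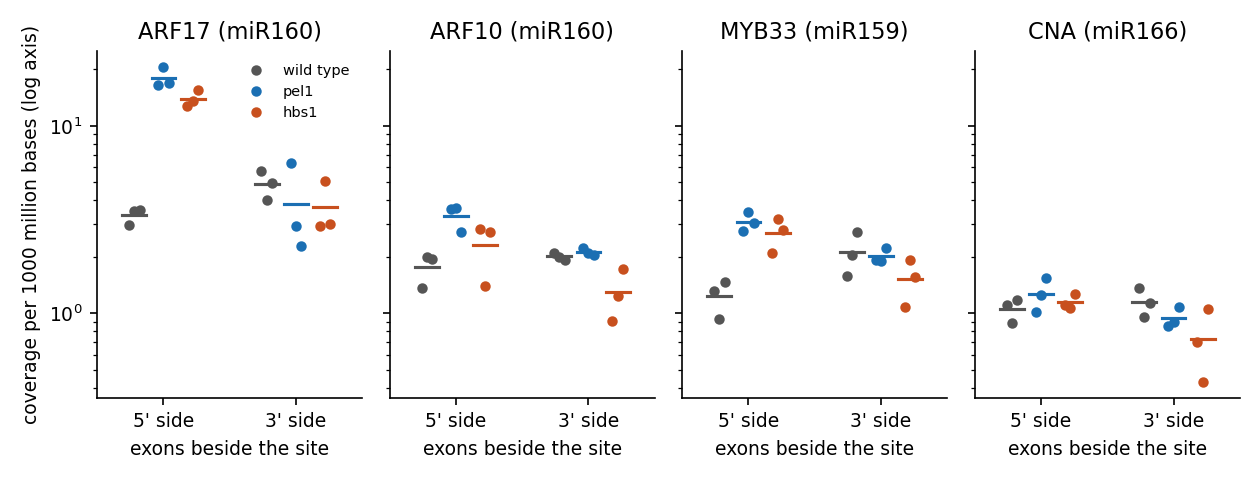
Coverage per Gb of aligned bases (log axis) over the exons upstream (5' side) and downstream (3' side) of the mapped cleavage site of ARF17, ARF10, MYB33 and CNA, with 1 point per library, the mean as a bar, and 3 libraries each of wild type, pel1 and hbs1. ARF17 5' coverage was 2.94 to 3.57 in the wild type and 12.8 to 20.7 in the mutants.

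In the authors' deposited table for Arabidopsis, ARF17 had the highest ratio in pel1 (4.04 relative to the wild type) and stood at 3.21 in hbs1, below HAM3 and SPL2. In the authors' deposited table the miR160 targets were above 1 in 3 of 3 cases in both mutants (median 2.18 and 2.24). There HAM3, a GRAS factor of meristem maintenance targeted by miR171, stood at 3.46 and 3.81, MYB33 at 2.32 and 1.90, and SPL2 at 1.61 and 3.32. Of 5 miR171 targets, 2 were above 1 in each mutant. Among these 5 a site was kept for HAM1, HAM2 and HAM3 (mismatch score 0 each). HAM2 and HAM3 were above 1 in both mutants, and HAM1 stood at 0.69 and 0.85. No site was kept for HK3 (score 11) and AT4G31860 (score 7), which were below 1 in both mutants. Among the 9 targets with a ratio per library, PHV (0.85 and 0.91) was below 1 in both mutants and TOE2 (1.15 and 0.81) in hbs1. The other targets of the 9 were above 1 in both. Across the whole authors' deposited table the effect was small: 46 of 73 targets were above 1 in pel1 (median 1.07, two-sided sign-flip permutation p = 0.15, adjusted 0.15). In hbs1 43 of 73 were (median 1.07, permutation p = 0.149, adjusted 0.15), and 1 target was listed at 0. The site search kept a site for 29 of the 75 listed targets, so these values include targets without a kept site. The 24 targets with a kept site in the coding region had medians of 1.175 in pel1 and 1.242 in hbs1 (mean log2 0.403 and 0.53). The 5 with a kept site in a UTR had medians of 0.949 and 1.098 (mean log2 -0.452 and 0.003). Neither group was tested against a ratio of 1. The log2 ratios of the mutants correlated across 72 targets in the authors' deposited table (Pearson r = 0.604, permutation p = 1e-05, Spearman rho = 0.596, permutation p = 1e-05, the smallest these permutations can give). Targets are not independent replicates, and the mutants share the wild-type libraries, which alone gave r = 0.53 over the 540 control genes in the library files, so part of the correlation may come from the shared controls.

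The place of the site did not separate the targets after adjustment. Of 29 Arabidopsis targets with a mapped site, 24 had it in the coding region and 5 in a UTR. In the authors' deposited table the mean log2 ratio of the first was higher by 0.86 in pel1 (two-sided permutation p = 0.0319 across targets, 0.0637 after Benjamini-Hochberg adjustment over both mutants). In hbs1 it was higher by 0.53 (permutation p = 0.118, adjusted 0.118). The UTR group held SPL3, NF-YA8, NF-YA3, AGO2 and NLA, and targets are not independent replicates.

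In N. benthamiana the same direction was seen in both silencing experiments. In the authors' deposited table, 41 of 57 targets had a 5'/3' ratio above 1 after Pelota silencing in experiment 1 (median 1.25, mean log2 0.47, SD 0.83 across targets, two-sided sign-flip permutation p = 8e-05, 0.00016 after Benjamini-Hochberg adjustment over the 4 tables). In experiment 2 it was 39 of 57 (median 1.41, mean log2 0.63, SD 1.02, sign-flip permutation p = 2e-05, adjusted 8e-05). These p-values treat targets as independent, although many share a miRNA family and all share the same libraries. They do not measure the spread between libraries. How the study chose these targets is not given in the sources used here, and if it chose them on these samples their direction is not independent evidence. The miR160 targets, auxin response factors, were above 1 in 8 of 8 cases in either experiment of the authors' deposited table (median 2.88 and 2.43). The miR171 targets, 6 of them SCL6 and 2 of them SCL15 homologues, were above 1 in 8 of 8 and 7 of 8 (median 1.85 and 3.70). The miR165 and miR166 targets were above 1 in 6 of 7 in both, miR396 targets in 1 of 6 and 5 of 6, and miR167 targets in 3 of 5 and 0 of 5. All 5 genes listed under miR167 were annotated as homocysteine methyltransferases. Under miR396 stood homologues of growth-regulating factors 3 (0.57 and 1.02) and 6 (0.47 and 4.90), THYLAKOID FORMATION1 genes, a tetratricopeptide repeat gene and an unannotated gene. Sites were not mapped in N. benthamiana, so the listed families were not checked here. Families of at least 3 targets differed from each other in experiment 1 (permutation p = 0.0001, the smallest possible, adjusted 0.0004 over the 4 tables, 9 families) and experiment 2 (p = 0.0008, adjusted 0.0016, 9 families). They did not differ detectably in pel1 (permutation p = 0.211, adjusted 0.211) or hbs1 (permutation p = 0.0732, adjusted 0.0976, 11 families each).

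In the authors' deposited table, the 5 targets with the smallest p in experiment 1 were 2 ARF16 homologues, 2 SCL6 homologues and a methyltransferase gene. They were Niben101Scf03206g01008.1 (ARF16, ratio 5.76, the authors' p = 0.00892), Niben101Scf00054g01013.1 (methyltransferase, 1.13, p = 0.0157), Niben101Scf01759g07006.1 (ARF16, 2.44, p = 0.0249), Niben101Scf03337g06007.1 (SCL6, 2.08, p = 0.0273) and Niben101Scf00317g11013.1 (SCL6, 1.86, p = 0.0468). In experiment 2 of the authors' deposited table they were Niben101Scf06123g07001.1 (ARF16, 4.30, p = 0.00118), Niben101Scf01759g04007.1 (REVOLUTA, 2.68, p = 0.00402), Niben101Scf02669g00003.1 (ARF18, 3.86, p = 0.00453), Niben101Scf09767g00005.1 (TRAUCO, 0.73, p = 0.00763) and Niben101Scf00317g11013.1 (SCL6, 6.72, p = 0.00797). Of the p-values given, 5 of 55 in experiment 1 and 12 of 52 in experiment 2 were under 0.05, 5 and 9 of them with a ratio above 1, and 0 passed the Benjamini-Hochberg adjustment in either experiment. The log2 ratios of the experiments, which have separate controls, correlated across the 57 targets (Pearson r = 0.40, permutation p = 0.00202, Spearman rho = 0.50, permutation p = 0.0001, adjusted over both pairs 0.00202 and 0.0001). There were 31 targets above 1 in both, 8 below 1 in both and 18 split. Targets are not independent replicates.

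**Figure D3:**
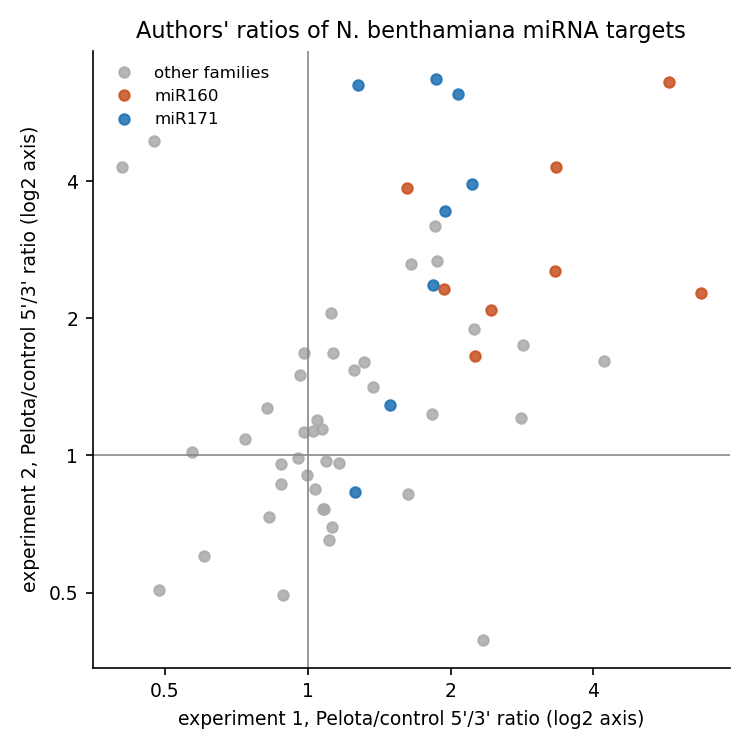
Ratios from the authors' deposited table for 57 N. benthamiana miRNA targets, experiment 1 against experiment 2 (log2 axes, ratio without units), with 1 point per target, miR160 and miR171 targets in colour and lines at 1. All 8 miR160 targets lie above 1 in both experiments.

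In gene TPM, ARF17 rose in both mutants (log2 1.43, SE 0.20, adjusted p = 0.00185 in pel1, and 1.19, SE 0.20, adjusted p = 0.00639 in hbs1, limma with Benjamini-Hochberg adjustment, n = 3 per group). Gene TPM sums full-length and partial transcripts. ARF17 coverage was higher upstream of the site alone, so a rise of full-length ARF17 is not shown. Of 62 measured miRNA targets in the list, 9 rose and 1 fell in pel1 and 52 did not pass (10 and 1 adjusted over the list alone). In hbs1 3 rose, 0 fell and 59 did not pass (4 and 0 adjusted over the list alone). In pel1 these included the AP2-type floral repressors TOE1 (log2 1.37, SE 0.25, adjusted p = 0.0102), AP2 (0.96, SE 0.22, adjusted p = 0.0299) and SNZ (1.16, SE 0.30, adjusted p = 0.048). The phase-change factor SPL2 rose too (1.39, SE 0.28, adjusted p = 0.0152). SMZ was listed at 0 TPM in all 3 wild-type libraries and at 1.51, 2.54 and 2.81 TPM in pel1. SPL3 fell by 1.1 on the log2 scale (SE 0.27, adjusted p = 0.0428). In hbs1 SNZ (1.94, SE 0.30, adjusted p = 0.00337) and SPL13A (1.38, SE 0.28, adjusted p = 0.0161) rose. The list as a whole, with 37 of 62 values positive in pel1 and 30 in hbs1, ranked higher than other genes in pel1 (camera adjusted p = 0.0204, 0.807 with an estimated correlation) and hbs1 (adjusted p = 0.0016, 0.931 with an estimated correlation). Its median in hbs1 was log2 -0.04 and its mean 0.10, against a median of -0.27 over all genes.

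The 8 largest increases in pel1 among genes with a symbol in the annotation were as follows. MAPKKK14, a MAP kinase kinase kinase gene that responds to wounding, rose most, from 3.57 ± 0.94 to 71.9 ± 4.35 TPM (log2 4.02, SE 0.30, adjusted p = 1.41e-05, limma with Benjamini-Hochberg adjustment, n = 3 per group). MAPKKK13 (2.85, SE 0.24, adjusted p = 5.2e-05) and MAPKKK15 (2.64, SE 0.34, adjusted p = 0.00103) rose beside it. The xyloglucan-modifying XTH18 rose by 3.76 (SE 0.47, adjusted p = 0.00169) and the pectin methylesterase ATPMEPCRB by 3.02 (SE 0.34, adjusted p = 0.000393). So did the AP2/ERF factor TNY, which restrains growth under drought (3.22, SE 0.27, adjusted p = 5.2e-05), RAS1, a salt and abscisic acid response gene (2.89, SE 0.27, adjusted p = 9.59e-05), and the gibberellin-inactivating GA2OX8 (2.75, SE 0.33, adjusted p = 0.000645).

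PEL1 aside, the largest decreases in pel1 among genes with a symbol in the annotation were in 7 genes. WRKY70, which balances salicylate and jasmonate defence, went from 51.8 ± 15.3 to 2.44 ± 0.73 TPM (log2 -3.93, SE 0.27, adjusted p = 6.82e-06, limma). The ethylene response factor ERF104 (-3.37, SE 0.32, adjusted p = 0.000112) and the chitin-induced ubiquitin ligase ATL2 (-3.07, SE 0.27, adjusted p = 6.52e-05) fell with it. So did the plasmodesmatal callose regulator CML41 (-2.99, SE 0.35, adjusted p = 0.000583) and WRKY33, needed for camalexin synthesis (-2.50, SE 0.27, adjusted p = 0.00027). The auxin repressor IAA29 (-2.98, SE 0.41, adjusted p = 0.00177) and the senescence factor NAP (-2.46, SE 0.57, adjusted p = 0.0482) were also lower. Of these and PEL1, NAP alone lost its call when a library was left out (it passed in 2 of 6 such fits).

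Among the fixed lists, 14 salicylate and immune genes had 0 that rose, 3 that fell (WRKY70, CBP60G with -2.13, SE 0.37, adjusted p = 0.00807, and PR2 with -2.33, SE 0.44, adjusted p = 0.0146) and 11 not passing in pel1. This list ranked lower than other genes (0 and 3 adjusted over the list alone, camera adjusted p = 0.0294, 0.807 with an estimated correlation). Of 12 cold and dehydration genes 2 rose, the dehydrin ERD10 (1.31, SE 0.25, adjusted p = 0.0131) and ERD7 (1.28, SE 0.27, adjusted p = 0.0191), and 0 fell. This list ranked higher (4 and 0 adjusted over the list alone, camera adjusted p = 0.0204, 0.807 with an estimated correlation). Of 15 jasmonate genes the lipoxygenase LOX4 rose (1.36, SE 0.35, adjusted p = 0.048) and 0 fell. LOX3 (1.88, SE 0.51, adjusted p = 0.0636) and the repressor JAZ10 (2.07, SE 0.57, adjusted p = 0.078) did not pass, nor did JAZ1, with a negative value (-0.70, SE 0.33, adjusted p = 0.273). This list, with 9 of 15 values positive, ranked higher too (3 and 0 adjusted over the list alone, camera adjusted p = 0.0294, 0.807 with an estimated correlation). The flowering factor FUL fell (-1.62, SE 0.39, adjusted p = 0.0398), 1 of 5 in its list.

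In all, 620 of 15925 genes passed in pel1, 321 higher and 299 lower (51.8% higher, 64.0% with median-centred values, 51.5% with quantile normalization, 80.1% with FPKM and 40.7% when rescaled over nuclear genes), and 4458 genes had no overlap between groups, where chance gives 10%. The median of all genes was log2 -0.09 with TPM as deposited, 0.02 when centred, 0.10 with FPKM and -0.12 over nuclear genes, so changes of that size carry no meaning here.

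In hbs1, MAPKKK14 again rose most, to 107 ± 39.6 TPM (log2 4.50, SE 0.30, adjusted p = 5.82e-06, limma with Benjamini-Hochberg adjustment, n = 3 per group). MAPKKK13 (3.52, SE 0.24, adjusted p = 7.99e-06) and RAS1 (3.28, SE 0.27, adjusted p = 3.98e-05) rose with it. Also among the 8 largest increases of genes with a symbol in the annotation was the sulfur-deficiency repressor of glucosinolate synthesis SDI1 (3.88, SE 0.35, adjusted p = 0.000104). So were the serine hydroxymethyltransferase SHM7 (3.36, SE 0.31, adjusted p = 9.22e-05) and LSU3, induced by low sulfur (3.26, SE 0.63, adjusted p = 0.0265). SRO5, an oxidative stress regulator (3.71, SE 0.32, adjusted p = 6.64e-05), and the defence factor WRKY18 (3.70, SE 0.35, adjusted p = 0.000109) rose too. Among such genes the largest decreases were those of MRD1, a gene lowered when methionine accumulates, from 28.6 ± 9.82 to 0.45 ± 0.42 TPM (log2 -4.34, SE 0.26, adjusted p = 5.82e-06), and ERF104 (-3.33, SE 0.32, adjusted p = 0.000109). Next came the B-box factor BBX17 (-3.03, SE 0.53, adjusted p = 0.0118) and the jasmonate sulfotransferase ST2A (-2.77, SE 0.65, adjusted p = 0.0483). IAA29 (-2.65, SE 0.41, adjusted p = 0.00398), the pectin methylesterase PME3 (-2.62, SE 0.47, adjusted p = 0.0116), WRKY70 (-2.50, SE 0.27, adjusted p = 0.000232) and the lipid transfer protein LTP2 (-2.35, SE 0.43, adjusted p = 0.0112) fell as well. BBX17, LSU3 and ST2A lost their calls without some single libraries (passing in 4, 3 and 2 of 6 such fits), and ST2A also with median-centred values (adjusted p = 0.0715).

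Of 15 jasmonate genes in hbs1, LOX4 rose (2.44, SE 0.35, adjusted p = 0.00211), 0 fell and 14 did not pass, among them OPR3 of jasmonate synthesis (1.22, SE 0.37, adjusted p = 0.0829). The list, with 10 of 15 values positive, ranked higher (2 and 0 adjusted over the list alone, camera adjusted p = 0.000354, 0.931 with an estimated correlation). Of 12 cold and dehydration genes, ERD10 (1.1, SE 0.25, adjusted p = 0.0297) and ERD7 (1.09, SE 0.27, adjusted p = 0.0379) rose and 0 fell. Their list, with 7 of 12 values positive, ranked higher as well (2 and 0 adjusted over the list alone, camera adjusted p = 0.0398, 0.931 with an estimated correlation). Of 14 salicylate and immune genes WRKY70 alone fell (camera adjusted p = 0.925). In total 676 of 15925 genes passed, 322 higher and 354 lower (47.6% higher, 75.9% with median-centred values, 67.3% with quantile normalization, 54.8% with FPKM and 59.6% over nuclear genes), and 3761 had no overlap between groups (10% by chance). The median of all genes was log2 -0.27 with TPM as deposited and -0.02 when centred, so decreases of hbs1 genes are to be read against that shift, which the largest ones exceed many times.

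The remaining lists passed camera in neither mutant against the wild type. In pel1 and hbs1 the adjusted p was 0.275 and 0.54 for anthocyanin synthesis (4 genes), 0.876 and 0.584 for the clock (13), and 0.964 and 0.554 for 5' decay and nonsense-mediated decay (16). It was 0.0853 and 0.666 for flowering markers (5), 0.28 and 0.54 for heat and protein folding (7), and 0.907 and 0.584 for iron (11). It was 0.104 and 0.925 for senescence (5), 0.969 and 0.34 for nonstop decay and exosome (18), and 0.812 and 0.368 for phosphate starvation (4). It was 0.958 and 0.925 for photosynthesis (25), 0.275 and 0.751 for RNA silencing machinery (21), and 0.275 and 0.584 for tasiRNA loci (3). Cytosolic ribosomal proteins (5) had 0.958 and 0.804, chloroplast-encoded genes (62) 0.958 and 0.476, and mitochondrion-encoded genes (84) 0.812 and 0.511. Within them FUL, NAP and the mitochondrial ATMG01110 (-2.43, SE 0.46, adjusted p = 0.0115) fell in pel1, and ATMG01110 (-2.71, SE 0.46, adjusted p = 0.00621) in hbs1. The root and seed lists were too small for camera: SCR (-0.34, adjusted p = 0.575), SHR (-0.05, adjusted p = 0.942) and SESA1 (1.34, adjusted p = 0.0689) did not pass in pel1. Nor did they in hbs1 (-0.50, adjusted p = 0.311, -0.39, adjusted p = 0.386, and 0.07, adjusted p = 0.927).

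Many genes passed in both mutants. Of the genes that passed in each, 112 were higher in both, where 6.49 are expected from the counts alone, 68 lower in both (6.65 expected) and 9 opposite (13.2 expected). MAPKKK14, MAPKKK13, RAS1, XTH18, LOX4 and ARF17 were among the first, and WRKY70, ERF104 and IAA29 among the second. Simulated groups without any change, set against the same 3 wild-type libraries, shared 0 in 20 draws, a value that leaves out the real changes and so does not show how many calls coincide through the shared controls. The log2 fold changes correlated across 15925 genes, which are not independent replicates, with Pearson r = 0.42 and Spearman rho = 0.34, but 100 simulated draws with the same controls gave r = 0.50. The covariance was 0.146 against 0.0829 simulated, a difference of 0.0629. The wild type has 3 libraries, too few for 2 per mutant, and they were not split into separate controls, so part of the excess may come from the shared controls.

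**Figure D4:**
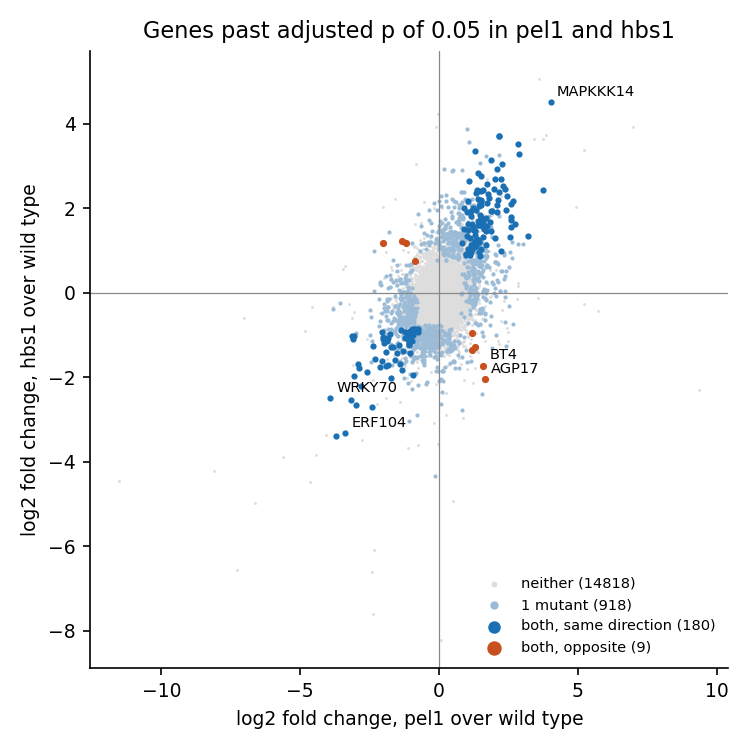
Log2 fold change over wild type of 15925 genes in pel1 (horizontal axis) and hbs1 (vertical axis), with 1 point per gene, coloured by whether it passed an adjusted p of 0.05 (limma) in neither, in 1 or in both mutants. MAPKKK14, at 4.02 and 4.50, lies highest among those that rose in both, and 9 genes passed in opposite directions.

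In the direct comparison of pel1 with hbs1, the chloroplast and cytosolic copper superoxide dismutases CSD2 (log2 3.68, SE 0.50, adjusted p = 0.00225) and CSD1 (2.29, SE 0.33, adjusted p = 0.00215) and their copper chaperone CCS (2.21, SE 0.30, adjusted p = 0.00149) were higher in pel1 (limma with Benjamini-Hochberg adjustment, n = 3 per group). All are miR398 targets. Each also rose in pel1 over the wild type (CSD2 2.42, adjusted p = 0.0227, CSD1 1.65, adjusted p = 0.0163, CCS 1.46, adjusted p = 0.018). Their decreases in hbs1 did not pass (-1.26, adjusted p = 0.174, -0.64, adjusted p = 0.276, and -0.75, adjusted p = 0.17). MRD1 (4.18, SE 0.26, adjusted p = 7.9e-06) and the arabinogalactan proteins AGP17 (3.69, SE 0.26, adjusted p = 1.34e-05) and AGP21 (3.23, SE 0.41, adjusted p = 0.0011) were higher in pel1. So were ST2A (3.60, SE 0.65, adjusted p = 0.015), the BTB scaffold protein BT4 (3.32, SE 0.32, adjusted p = 0.000169), the myrosinase TGG2 (3.25, SE 0.77, adjusted p = 0.0463) and the flowering activator AGL19 (3.07, SE 0.32, adjusted p = 0.000333). Lower in pel1 than in hbs1 were the ethylene factors ERF2 (-3.32, SE 0.31, adjusted p = 0.000165) and ERF53 (-2.74, SE 0.40, adjusted p = 0.00225), the salt-induced SIS (-3.23, SE 0.44, adjusted p = 0.00225) and SDI1 (-2.87, SE 0.35, adjusted p = 0.00103). Also lower were the receptor kinase RK1 (-2.70, SE 0.61, adjusted p = 0.0346), DIP2 (-2.48, SE 0.44, adjusted p = 0.00671) and the metal-nicotianamine transporter YSL2 (-2.43, SE 0.27, adjusted p = 0.000415). RK1 lost its call without any single library (0 of 6 such fits passed), and TGG2 and ST2A without some (1 and 3 of 6 passed).

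Of 14 salicylate and immune genes 0 were higher and 3 lower in pel1 than in hbs1, WRKY70 (-1.43, SE 0.27, adjusted p = 0.00893), PR2 (-2.38, SE 0.44, adjusted p = 0.0102) and CBP60G (-1.46, SE 0.37, adjusted p = 0.041). The list ranked lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.0175, 0.495 with an estimated correlation). The 5 flowering markers also ranked lower (camera adjusted p = 0.0316, 0.46 with an estimated correlation), with 0 passing singly (0 and 1 adjusted over the list alone). Of the 62 miRNA targets the 3 miR398 targets were higher and NF-YA10 lower (-1.39, SE 0.36, adjusted p = 0.0417) (4 and 1 adjusted over the list alone, camera adjusted p = 0.757). The jasmonate repressor JAZ1 was lower (-1.33, SE 0.33, adjusted p = 0.0341) and the clock gene ELF3 higher (1.32, SE 0.28, adjusted p = 0.0171) in pel1. In total 943 genes passed, 582 higher and 361 lower in pel1 (61.7% higher, 49.1% with median-centred values, 48.9% with quantile normalization, 80.4% with FPKM and 46.2% over nuclear genes), with a median of log2 0.16 over all genes (0.01 when centred) and 4784 genes without overlap (10% by chance). The share higher in pel1 was 83.6% without hbs1 replicate 1 and 49.8% without hbs1 replicate 2, so it depended on single libraries.

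In N. benthamiana experiment 1, 1506 of 12844 genes differed between Pelota-silenced and PDS-silenced plants (limma with Benjamini-Hochberg adjustment, n = 3 per group). PDS silencing was the only control, so effects of silencing Pelota and of silencing PDS cannot be told apart. The 1506 split into 628 higher and 878 lower after Pelota silencing, and 3546 of the genes tested had no overlap (10% by chance). The files give no names for these genes. The largest changes were in Niben101Scf00163g22002 (log2 4.61, SE 0.23, adjusted p = 1.01e-06) and Niben101Scf16007g00010 (4.40, SE 0.22, adjusted p = 1.01e-06), which rose. Among decreases they were Niben101Scf10126g00007 (-4.37, SE 0.25, adjusted p = 2.06e-06) and Niben101Scf00199g05008 (-4.32, SE 0.24, adjusted p = 2.06e-06). Of 14 measured genes of the authors' deposited table of miRNA targets 3 rose, 1 fell and 10 did not pass (4 and 1 adjusted over the list alone, camera p = 0.052, 0.389 with an estimated correlation). If the study chose that list on these samples, it is not independent evidence. The risers included the ARF16 homologues Niben101Scf03206g01008 (1.09, SE 0.23, adjusted p = 0.011) and Niben101Scf01759g07006 (0.85, SE 0.22, adjusted p = 0.0301), both of which lost their calls without single libraries. The decrease was that of Niben101Scf01812g02025 (-1.25, SE 0.23, adjusted p = 0.0041).

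In experiment 2, with 554.7 to 2131 Mb of aligned bases per library, 4 of 9650 genes passed, all higher after Pelota silencing (limma, n = 3 per group). Depth was unequal between these groups, at 554.7, 630.4 and 1585.5 Mb in the controls and 1834.7, 2131 and 965.5 Mb after Pelota silencing. Without Pelota replicate 6, 0 were higher and 2 lower, and without replicate 4 or 5, 0 passed. In the full fit 473 were under an unadjusted p of 0.05, and 731 had no overlap (10% by chance). Of the 4, Niben101Scf03403g02009 was listed at 0 TPM in all 3 controls and at 257.5, 321 and 363.3 TPM after silencing, and Niben101Scf05750g00006 at 0 in the controls and 106.3, 73.4 and 78.0 TPM after silencing. In this experiment 487 genes with a mean TPM of at least 5 were listed at 0 in some library. A value of 0 in the controls therefore cannot be told from a transcript that was not assembled. In experiment 1 both genes varied within groups instead (Niben101Scf03403g02009 at 108.2, 2.80 and 3.03 TPM in controls and 3.0, 119.3 and 2.21 TPM after silencing). Of the authors' miRNA targets 9 were measured, 0 passed in limma, 1 was under an unadjusted p of 0.05, and the list did not pass camera. Across 8662 genes measured in both experiments the log2 fold changes correlated weakly (Pearson r = 0.25, Spearman rho = 0.23, genes not being independent replicates). Among the 1131 of them that passed in experiment 1, r was 0.54 and 874 (77.3%) had the same sign in experiment 2.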

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

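The test of pel1 against hbs1 was planned, and the choice of the genes below, and the test of the difference between the N. benthamiana experiments, were made after the results were seen. Beside the result per comparison stand the other splits of its 6 libraries into 3 and 3. With 10 splits a share under 0.05 is out of reach. The real split was the 1 split with as many genes in pel1 against wild type (620, highest other 2), hbs1 against wild type (676, highest other 2), pel1 against hbs1 (943, highest other 1) and experiment 1 (1506, highest other 4). In experiment 2, 2 of the 10 splits, the real one included, had as many genes (4, highest other 15). A split with several times the real count points to a structure of these samples, whose source was not tested.

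There were 9 genes that passed in pel1 and in hbs1 with opposite signs, which is not above the 13.2 expected from the counts alone. That expectation treats the calls in the mutants as independent, although the mutants share the wild-type libraries. It therefore cannot decide whether 9 is more than chance gives. The difference of these 9 genes between the mutants (limma with Benjamini-Hochberg adjustment, n = 3 libraries per group) follows from this choice of genes, so its p adds no evidence. Higher in pel1 and lower in hbs1 than in the wild type were AGP17 (difference log2 3.69, adjusted p = 1.34e-05, 17.1 ± 4.98 TPM in wild type, 54.0 ± 0.96 in pel1, 3.37 ± 1.2 in hbs1) and BT4 (3.32, adjusted p = 0.000169). So were AT4G26540 (2.57, adjusted p = 0.000165), the B-box factor BZS1 (2.55, adjusted p = 0.000815) and AT4G37530 (2.15, adjusted p = 0.000165). Lower in pel1 and higher in hbs1 were AT2G47880 (-3.21, adjusted p = 7.92e-05), AT5G41750 (-2.56, adjusted p = 0.000921) and the abscisic acid synthesis gene NCED3 (-2.36, adjusted p = 0.000398, 14.9 ± 3.88 TPM in wild type, 5.92 ± 1.22 in pel1, 34.6 ± 7.71 in hbs1). The other was the tocopherol methyltransferase G-TMT (-1.60, adjusted p = 0.000921). Of the calls against the wild type, both passed in all 6 fits without 1 library for AGP17 alone. In pel1 the number of fits that passed was 6 for AT2G47880 and AT4G37530, 3 for BT4 and AT4G26540, 2 for AT5G41750, 1 for NCED3 and G-TMT and 0 for BZS1. In hbs1 it was 6 for BT4, 5 for AT4G26540, 3 for AT4G37530, 2 for AT2G47880, NCED3, BZS1 and AT5G41750 and 0 for G-TMT. No technical or biological explanation of these genes was tested.

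The difference between Pelota-silenced and PDS-silenced plants varied between the N. benthamiana experiments for 38 of 14181 genes (limma interaction, 4 higher and 34 lower in experiment 1), 21 of them among the 1506 genes that passed in experiment 1. Both experiments shared a single fit and spread here, although library correlations within groups were 0.922 to 0.96 in experiment 1 and 0.678 to 0.839 in experiment 2. Only 8662 genes were measured in both, so a gene missing from an experiment could count as differing. The experiments differed in library kit, depth and, per the labels, read processing at once, so these sources cannot be told apart, and no biological explanation was tested.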

How the results depend on the processing

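Values for nuclear genes, for transcripts matching the reference alone, for genes above 0 in every library, for median-centred lists, for strict sites and for subtracted background were chosen after the data were seen. Counts of changed genes moved with scaling. FPKM gave 1837 (pel1), 1218 (hbs1) and 3145 (pel1 against hbs1) genes, median-centred values 1471, 1134 and 1939, quantile normalization 1491, 1099 and 2011, and rescaling over nuclear genes 1682, 1096 and 2031. The authors' deposited table counted 3454 (pel1), 2493 (hbs1), 7133 (experiment 1) and 87 (experiment 2), over more and merged loci. Calls also differed on named genes present in both analyses (378 in Arabidopsis). Of the authors' 39 calls there in pel1 and 35 in hbs1, 34 and 33 had the same sign here, but 2 and 1 passed. The log2 fold changes of these genes had Spearman rho = 0.63 and 0.64. In experiment 1, over 35 genes, 2 of 4 had the same sign and 1 passed (rho = 0.29). The spread of 6 libraries alone gave 352 genes for hbs1. TPM of at least 5 gave 876 in experiment 1, where fewer genes were tested, and in experiment 2 no filter gave 2 and genes above 0 in every library 2. Of the 620, 676 and 943 calls, 591, 542 and 877 still passed with median-centred values. The cause of the other moves was not tested.

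Without single libraries the counts ranged from 227 to 712 for pel1 (227 without wild type 1, 231, 233 and 273 without pel1 1, 2 and 3). They ranged from 298 to 1069 for hbs1 (338 and 426 without wild type 1 and 3, 1069, 298 and 438 without hbs1 1, 2 and 3). For pel1 against hbs1 they ranged from 310 to 1767 (1767, 504 and 397 without hbs1 1, 2 and 3, 310, 420 and 374 without pel1 1, 2 and 3). They ranged from 775 to 2236 in experiment 1 (810 and 775 without control 1 and 2, 899 without Pelota 2) and from 0 to 10 in experiment 2 (10 without control 6, 0, 0 and 2 without Pelota 4, 5 and 6, those 2 lower). Without hbs1 1 the split for hbs1 was 250 higher and 819 lower, and that for pel1 against hbs1 was 1478 higher and 289 lower. Without hbs1 2 the split for pel1 against hbs1 was 251 higher and 253 lower.

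Of the lists, 4, 3 and 2 passed for pel1, hbs1 and pel1 against hbs1. With an estimated correlation 0, 0 and 0 did, with median-centred values 0, 2 and 0, and 1 in experiment 1 (0 before). With the replicate block 6, 2 and 2 did: flowering (camera adjusted p = 0.0366) and senescence (0.0253) gained a call in pel1, and cold and dehydration lost it in hbs1 (0.0564). The correlation of the experiments was 0.25, and 0.54 among genes that passed in experiment 1, and that of the mutants was 0.48 to 0.49 without single wild-type libraries, with a covariance difference of 0.0629.

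The 5'/3' ratio of the mutants against the wild type kept its direction under each alternative. A pseudocount of 10 gave 0.43 for pel1 and 0.50 for hbs1. Leaving out libraries gave 0.62 to 0.76, 0.70 to 1.03 and, for pel1 against hbs1, -0.33 to 0.004. Single targets passing went from 2 to 1 (pel1) and from 4 to 1 (hbs1) relative to the library median over targets (ARF17 alone in each), and to 2 in hbs1 with a pseudocount of 10. They lay at 2 to 3, 2 to 5 and 0 to 0 without single libraries (2 without wild type 1, 2 or 3 or hbs1 1). Relative to the library median CNA turned to -0.11 in hbs1.

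With the replicate block, hbs1 had 2 single targets. The numbers do not pair the libraries: residual correlations of equal numbers were -0.086 to 0.096 in Arabidopsis, so the block was not used. Among 389 values for single genes and targets, 3792 recomputed values held 3535 on the same side, 91 that lost and 165 that gained a call and 1 reversed, and 2288 values without single libraries held 2061, 191, 36 and 0. Depth was lowest in experiment 2 (554.7 to 2131 Mb), where 0% of simulated changes of log2 2 were recovered at its spread between libraries. Whether depth, kit or read processing limits it was not tested.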

Other observations

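All tests of explanations in this part were chosen after the results were seen. The 5'/3' coverage ratio of 9 miRNA targets was higher by log2 0.70 in pel1 and 0.91 in hbs1. A 5' skew of whole libraries is argued against by the other multi-exon genes, whose median moved by 0.0303 and 0.0314. For the mean over the 9 targets, noise of genes at this coverage is argued against by 2 (pel1) and 0 (hbs1) of 10000 matched sets that changed as much. The sets were not matched on the length of the sides (231 bases downstream in ARF17, 205 upstream in AGO1), so noise of short sides was not tested. That mean rested most on ARF17 and MYB33, so the sets do not speak for each target. A single library is argued against by lowest values of 0.62 and 0.70 with 1 library left out. More 5' cleavage product without nonstop decay remains a candidate explanation: relative to control genes the 5' side was higher by 0.64 and 0.56, with 3' sides at -0.03 and -0.32. In hbs1 the 3' value varied between libraries (SD 0.55, exact two-sided permutation p = 0.5), so a change on that side was neither shown nor excluded. Reads shared between related genes, other transcript starts and altered miRNA levels were not tested and stay open.

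SDI1, LSU3 and SHM7 among the largest increases of genes with a symbol in hbs1 led to the hypothesis of a sulfur limitation response in hbs1. It was set against 11 other measured genes of a list of 17. The list was chosen after values were seen and rests on the same libraries, so its p-values are not independent evidence. Of the 11, 6 rose (SDI2 3.06, LSU1 3.24, APR1 1.81, APR2 1.48, APR3 2.82 and GGCT2;1 3.55, log2, limma), 10 had a positive change and the median was 1.51 (camera p = 3.31e-13, 0.0147 with an estimated correlation). LSU2 (1.51), LSU4 (0.75) and the sulfate transporter genes SULTR1;2 (0.41), SULTR4;2 (0.28) and SULTR2;1 (-0.02) did not pass. A single library is argued against by the lowest median of 1.09 with 1 library left out, although 4 genes were the fewest to rise in such fits. LSU1 passed in 4 of 6 of them, APR1 in 5 and APR2 in 1. In pel1 0 of the 11 rose (median 0.75, camera p = 0.00258, 0.21 with an estimated correlation). Pel1 against hbs1 gave a median of -1.04 (camera p = 4.74e-07, 0.0576 with an estimated correlation), with 0 of 11 values positive. APR2 alone passed lower there (-1.37, adjusted p = 0.0411, limma). A difference between the mutants is not shown with the estimated correlation. Of the genes that led to the list, SHM7 also rose in pel1 (1.29, adjusted p = 0.0336, limma), a call that passed in 0 of 6 fits without 1 library. Such a response may reflect the mutation or the growth of these plants, which the labels do not separate.

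Next to PEL1 on chromosome 4, AT4G27652 (13809779 to 13810462), AT4G27654 (13811612 to 13812126) and AT4G27657 (13812989 to 13813701), chosen after their values were seen, were higher in both mutants. The changes were log2 2.59, 2.39 and 1.46 in pel1 (adjusted p = 0.000165, 0.00226 and 0.0227, limma) and 1.72, 2.45 and 1.21 in hbs1 (adjusted p = 0.00288, 0.00207 and 0.0495). AT4G27657 passed in 2 (pel1) and 1 (hbs1) of the 6 fits without 1 library, and the other genes in 6.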
